A study of Arabidopsis thaliana with 36 samples.

How the data were processed

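Seedlings of the Arabidopsis thaliana accession Col-0, of a hy5 mutant and of a phyAB mutant were grown at 21 °C or 27 °C by day, and roots and shoots were collected apart. HY5 is a bZIP transcription factor of light signalling, and PHYA and PHYB are the red and far-red light receptors phytochrome A and B. Each of the 12 groups, formed by 3 genotypes, 2 tissues and 2 temperatures, has 3 replicates, which gives 36 libraries. Per the labels' protocols, days had 16 h of light, nights of 8 h were at 15 °C or 21 °C, and tissue was taken 6 days after germination. The time at the higher temperature is given in conflicting ways, as 4 h in the title and design and as 3 days in the treatment protocol, so the length of the treatment is not known here. Mutant alleles are not given in the sources used here, and nothing in the labels says whether replicates are separately grown cultures. If they are not, the spread between replicates is narrower than that between cultures. The phyAB root libraries numbered 3, at both temperatures, are called root by title and tissue and shoot by their source name. They were used as root, which their root marker levels fit.

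Per the labels' protocols, total RNA went into stranded mRNA libraries, which were sequenced as single reads of 50 bases. Per the submitters' processing notes, read quality was looked at with FastQC, reads were aligned to the TAIR10 build with TopHat2, reads per gene were counted with HTSeq, and edgeR was used afterwards. Tool versions and the strand setting of the counting are not given in the sources used here, so overlapping antisense transcripts may enter a gene's value. The values used are the deposited counts, which are whole numbers of reads per gene from the authors' counting, before any scaling. The deposited files held counts for 32833 genes in every library, of which 32548 have an entry in the TAIR10.1 annotation used for gene names and 10804 have a symbol there. Locus identifiers are given for genes whose symbol is shared or absent.

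Reads counted in genes came to 14810514 to 24006279 per root library and to 17008543 to 23880472 per shoot library. CPM gives a gene's reads per 1000000 counted reads, so that a gene at 1 CPM has about 20 reads in a library, and counting noise is large below that level. Between replicates, chi-square per degree of freedom over genes was 3.27 to 15.2 in 36 pairs, which is above counting noise in each of these pairs of replicates. The 5 summary categories that follow the genes were left out of library sizes and tests. Reads that aligned at more than 1 place were 5.00% to 10.4% in roots and 8.29% to 34.6% in shoots. Reads outside any gene were 1.17% to 1.81% in roots and 0.697% to 1.51% in shoots, and reads in overlapping genes 0.186% to 0.299% and 0.0570% to 0.0930%. Reads at more than 1 place are not counted, so genes with near-identical copies, such as those of the LHCB1 and RBCS families, are read only through the bases in which the copies differ.

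Counts were analysed with edgeR 4.0.16 in R 4.3.3. One model was fitted to the 18 root libraries and one to the 18 shoot libraries, with the 6 groups of each tissue as the only term, TMM factors and the default filter on low counts, which left 20355 genes in roots and 20100 in shoots. A model of all 36 libraries, with 21598 genes, served for the difference of the temperature response between tissues. The common biological coefficient of variation was 0.0800 in roots, 0.0910 in shoots and 0.0850 in the joint model. Tests were edgeR's quasi-likelihood tests, and p-values were adjusted over all genes of a contrast by the Benjamini-Hochberg method, with 0.05 as the threshold. Of 19 contrasts, 6 compare 27 °C with 21 °C, 8 compare a mutant with Col-0 at 1 temperature, and 5 are differences of temperature responses. Levels are CPM scaled with the TMM factors of the tissue, as mean ± SD with n = 3 per group, and log2 fold changes stand with their standard error (SE). The factors of the joint model were used instead for marker levels per library, summed seed transcripts, ranges of single seed genes over libraries, loci that mark a mutant line and shares of shoot RNA in roots. CPM of shoot libraries on these scales cannot be set side by side.

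Gene lists were written before the data were examined, as 435 pairs of symbol and locus in 22 lists. Of these, 434 were kept, 10 of them without a symbol in the reference, and 1 was dropped because the reference gives it another symbol. The lists are heat shock proteins and factors, endoplasmic reticulum unfolded protein response, auxin synthesis and transport, auxin response, PIF pathway and shade response, HY5-linked light signalling, flavonoid and anthocyanin synthesis, photosynthesis and chlorophyll (also used as shoot markers), root markers, root hair, endodermis and suberin, cell cycle, circadian clock, cold response, brassinosteroid, gibberellin, salicylic acid and immunity, jasmonate, abscisic acid and dehydration, iron deficiency, nitrate, and ribosome biogenesis. Each was tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, with Benjamini-Hochberg adjustment over the lists of a contrast, then with an estimated correlation. Members passing the test were counted with adjustment over all genes and adjusted over the list alone.

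Named genes follow a rule fixed at the same time. It takes HY5, PHYA and PHYB, the 10 largest rises and 10 largest falls of the Col-0 temperature response in each tissue, and 5 each way in other contrasts. These had to pass the threshold, to have a symbol and a mean of at least 2 CPM over the libraries compared, and, outside the difference contrasts, to show no overlap between the 3 and 3 libraries. From each list come up to 4 members with the smallest adjusted p. With 3 against 3 libraries, chance gives no overlap for 10% of genes.

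Whether replicate numbers pair libraries was read from the correlation of same-numbered libraries' deviations from their group means. All 3 correlations were above 0.1 for the temperature response of phyAB roots (0.142, 0.135 and 0.151) and, in shoots at 27 °C, for hy5 against Col-0 (0.130, 0.176 and 0.329) and phyAB against Col-0 (0.195, 0.117 and 0.311), so the data alone pair these. The number of calls was tested on simulated data with 200 changed genes. For the Col-0 root temperature response, among 20231 genes, 62.7% of genes changed 1.5-fold, 88.1% 2-fold and 100% 4-fold were called, with 14 unchanged genes. The hy5 root difference gave 43.3%, 76.1% and 98.5%, with 4. The Col-0 shoot response, among 19965 genes, gave 76.1%, 85.1% and 98.5% with 8, and the hy5 shoot difference 46.3%, 79.1% and 93.9% with 3. Camera called the raised set and 0 of 21 random sets, which does not test lists of correlated genes.

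Overlaps count genes called in the same direction in a pair of contrasts. For mutants that share Col-0 libraries, 20 simulations of unchanged mutants against the same controls gave the correlation that sharing alone brings. Alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, a block for the replicate number, only the libraries of the groups compared, stricter thresholds for overlaps, and leaving out each library in turn and both libraries with conflicting tissue labels. Leaving out the phyAB roots numbered 2, and the shoots numbered 3, was added after the data were seen. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared tables and figures. Mapping positions of reads, which could show what is left of each mutated gene, were not used here.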

Results

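The libraries ask how roots and shoots of young seedlings respond to warmer days and nights. They also ask whether the response differs in hy5 mutants, named for a light signalling factor, or in phyAB mutants, named for the phytochromes A and B. Each value rests on 14810514 to 24006279 counted reads per library and on 3 libraries per group. Adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named.

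Transcripts of the mutated genes were read first. HY5 (AT5G11260, chromosome 5) stood at 48.5 ± 4.97 CPM (SD, n = 3) in Col-0 roots at 21 °C and at 12.4 ± 0.705 CPM in hy5 roots, a log2 fold change of -1.96. At 27 °C the root values were 48.5 ± 2.27 and 12.9 ± 1.55 CPM. In shoots HY5 was low in every genotype, and its difference between hy5 and Col-0 did not pass, with 7.75 ± 2.07 CPM in Col-0 and 7.62 ± 0.449 CPM in hy5 at 21 °C (adjusted p = 0.938, edgeR). The values were 7.32 ± 0.694 against 5.67 ± 0.471 CPM at 27 °C (adjusted p = 0.230, edgeR), where the hy5 libraries (up to 6.204 CPM) lay below those of Col-0 (from 6.533 CPM) without overlap. In phyAB roots HY5 fell to 24.2 ± 3.21 CPM at 21 °C and 18.7 ± 1.22 CPM at 27 °C. PHYA (AT1G09570, chromosome 1) fell in phyAB in both tissues, from 138 ± 3.78 to 16.5 ± 2.28 CPM in roots and from 72.1 ± 6.6 to 18.7 ± 2.09 CPM in shoots at 21 °C. PHYB (AT2G18790, chromosome 2) fell in phyAB roots from 116 ± 4.15 to 41.2 ± 2.69 CPM at 21 °C. Its change in phyAB shoots was small, from 79.4 ± 9.04 to 61.0 ± 0.879 CPM at 21 °C (log2 fold change -0.38, adjusted p = 0.000426, edgeR), and at 27 °C it did not pass, with 68.1 ± 3.61 against 60.4 ± 3.79 CPM (adjusted p = 0.0621, edgeR). A transcript that remains does not tell whether it gives a working protein, and alleles are not given in the sources used here.

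**Figure D1:**
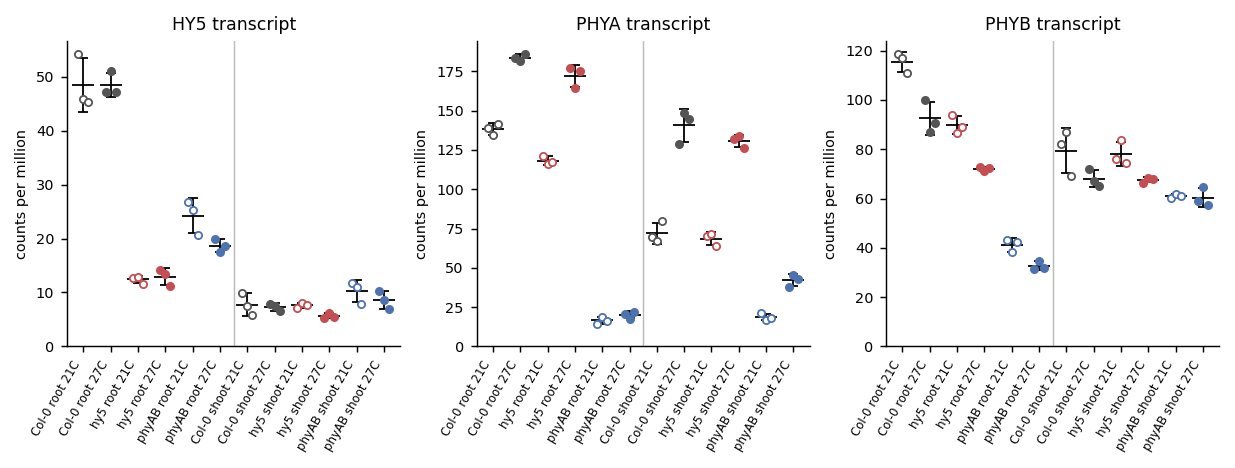
HY5, PHYA and PHYB transcript in CPM in the 12 groups, roots left and shoots right of the grey line. Each point is 1 library, open at 21 °C and filled at 27 °C, in grey for Col-0, red for hy5 and blue for phyAB, and bars give mean ± SD with n = 3.

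Tissue labels were checked with marker genes. The mean log2 CPM of the photosynthesis genes was -0.19 to 3.61 in the 18 root libraries and 11.28 to 11.88 in the 18 shoot libraries, and that of the root markers was 5.04 to 5.69 in roots and 0.38 to 1.94 in shoots. Both phyAB root libraries with conflicting labels fell within the root ranges. Seed storage and oil body transcripts set the phyAB shoots apart. The summed level of 18 such genes was 476, 1190 and 3250 CPM in the phyAB shoots at 21 °C and 287, 706 and 1700 CPM at 27 °C, against 3.64 to 5.94 CPM in Col-0 shoots, 8.49 to 20.25 CPM in hy5 shoots and at most 2.60 CPM in any phyAB root. These sums use the factors of the joint model, and the list was written after the data were seen. Shoot libraries numbered 3 at 27 °C also held the largest shares of reads at more than 1 place, with 27.8% in Col-0, 34.6% in hy5 and 28.8% in phyAB.

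**Figure D2:**
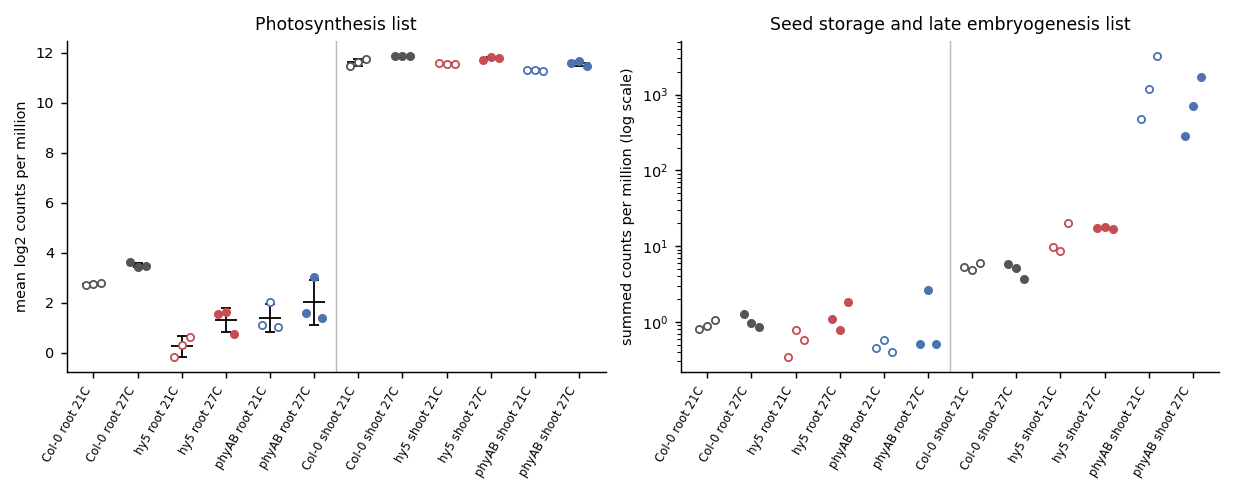
Left, mean log2 CPM of the photosynthesis genes in each library, with mean ± SD of n = 3. Right, summed CPM of 18 seed genes in each library on a log scale, without error bars. Each point is 1 library, with colours for genotype and open or filled points for 21 °C or 27 °C.

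In Col-0 roots heat shock genes were mostly higher at 27 °C, and most genes of the nitrate list were lower. HSP90.1 (AT5G52640), a cytosolic chaperone, rose from 11 ± 0.85 to 98 ± 18 CPM (log2 fold change 3.16 ± 0.15 SE, adjusted p = 1.75e-10). HSP17.4 (AT3G46230), a small heat shock protein, rose from 0.559 ± 0.190 to 7.07 ± 2.04 CPM. MBF1C (AT3G24500), a coactivator of the heat response, rose from 8.98 ± 0.528 to 58.3 ± 10.8 CPM. The sucrose exporters SWEET11 (AT3G48740) and SWEET12 (AT5G23660) rose by 3.18 ± 0.46 and 3.11 ± 0.50. DYL1 (AT1G28330), a gene of dormant buds, rose from 25.9 ± 6.63 to 179 ± 42.5 CPM. On the other side, CYP82C4 (AT4G31940), a cytochrome P450 of iron-limited roots, fell from 92.5 ± 16.8 to 3.38 ± 1.48 CPM (log2 fold change -4.78 ± 0.48, adjusted p = 4.56e-07).

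Further large rises in Col-0 roots were those of TPX2 (AT1G65970), a peroxiredoxin, at 2.92 ± 0.27, SNG1 (AT2G22990; 2.80 ± 0.33), which makes sinapoylmalate, and TIN1 (AT5G64510), from 1.72 ± 0.146 to 11.2 ± 2.81 CPM. The glutathione transferase GSTF14 (AT1G49860) fell by 3.27, the nitrile specifier NSP3 (AT3G16390) from 75.1 ± 3.70 to 9.67 ± 2.45 CPM, and the cell wall enzyme XTH20 (AT5G48070) from 34.6 ± 5.59 to 5.21 ± 1.09 CPM. Among further falls were CYP83A1 (AT4G13770) at 39.0 ± 10.3 CPM after 166 ± 19.9, FMO GS-OX3 (AT1G62560) at 1.02 ± 0.665 CPM after 6.71 ± 0.919, and UGT84A1 (AT4G15480) with a log2 fold change of -2.45 ± 0.15. In all, 8857 of 20355 genes passed, 4415 higher and 4442 lower at 27 °C, of which 638 and 367 changed at least 2-fold.

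By group, 25 of 30 measured heat shock genes rose and 1 fell in Col-0 roots, and adjusted over the list alone the counts were 27 and 1. Hop3 (AT4G12400), a co-chaperone, rose from 21.7 to 97.5 CPM (log2 fold change 2.17 ± 0.08), and the immunophilin AT5G48570 by 2.83 ± 0.11. Camera called the list up at adjusted p = 4.94e-14, and adjusted p = 0.132 with an estimated correlation. Of 15 genes of the unfolded protein response, 8 rose and 0 fell (9 and 0 adjusted over the list alone), among them the ER chaperone BIP3 (AT1G09080; 0.370 ± 0.104 to 4.08 ± 0.823 CPM) and ATERDJ3A (AT3G08970; 1.75 ± 0.14). Camera called this list at adjusted p = 0.00396, and adjusted p = 0.536 with an estimated correlation. Photosynthesis genes rose in roots, 27 of 40 with 0 lower by either adjustment, such as LHCB4.1 (AT5G01530; 17.5 to 47.8 CPM), LHCA4 (AT3G47470; 59.8 to 147 CPM) and the chloroplast regulator GLK2 (AT5G44190; 0.85 ± 0.13). The list's camera test gave adjusted p = 0.000164, and adjusted p = 0.536 with an estimated correlation. Their mean log2 CPM in roots is at most 3.61, far below shoots. Of 14 salicylic acid and immunity genes, 7 rose and 0 fell by either adjustment, with WRKY70 (AT3G56400) up by 1.68 ± 0.22 and EDS16 (AT1G74710), which makes salicylic acid precursors, up by 0.60 ± 0.11. For this list camera gave adjusted p = 0.0123, and adjusted p = 0.536 with an estimated correlation.

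Ribosome biogenesis genes fell together in Col-0 roots, 13 of 13 by either adjustment. FIB2 (AT4G25630), a fibrillarin, fell from 286 to 117 CPM (log2 fold change -1.29 ± 0.09), NSN1 (AT3G07050) from 190 to 88.5 CPM and the nucleolin NUC-L1 (AT1G48920) from 845 to 444 CPM. By camera the list had adjusted p = 1.65e-10, and adjusted p = 0.331 with an estimated correlation. Of 13 nitrate genes, 10 fell and 1 rose (11 and 1 adjusted over the list alone), among them the transporter NRT2:1 (AT1G08090; 24.5 ± 10.4 to 3.6 ± 1.2 CPM), G6PD3 (AT1G24280; -1.13 ± 0.09) and the nitrite reductase NIR1 (AT2G15620; 439 to 191 CPM). Tested with camera, the list had adjusted p = 6.45e-06, and adjusted p = 0.187 with an estimated correlation. Iron deficiency genes showed 8 falls and 2 rises of 15 by either adjustment, with the iron transporter IRT1 (AT4G19690) going from 246 ± 24.8 to 31.1 ± 5.77 CPM, the reductase FRO2 (AT1G01580) from 113 ± 33.1 to 17.9 ± 3.68 CPM and the regulator FRU (AT2G28160) from 105 to 56.0 CPM. Its camera test had adjusted p = 0.0123, and adjusted p = 0.536 with an estimated correlation. Flavonoid genes fell in 7 of 8 cases with 0 higher by either adjustment, such as TT5 (AT3G55120), chalcone isomerase, by 1.95 ± 0.14. With camera, that list had adjusted p = 0.0295, and adjusted p = 0.536 with an estimated correlation. Cold response genes fell in 8 of 13 with 0 higher by either adjustment, with ERD10 (AT1G20450) at 743 CPM before and 387 CPM after and GolS3 (AT1G09350), a galactinol synthase, lower by 1.52 ± 0.17. Camera's result for it was adjusted p = 0.0238, and adjusted p = 0.522 with an estimated correlation. Of 31 cell cycle genes 13 fell and 0 rose (16 and 0 adjusted over the list alone), among them the replication helicase subunits MCM6 (AT5G44635; -0.44 ± 0.07) and MCM3 (AT5G46280; -0.37 ± 0.08). In camera this list had adjusted p = 0.00396, and adjusted p = 0.536 with an estimated correlation.

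The other 12 lists did not pass camera in Col-0 roots. Members that changed include PRR7 (AT5G02810; 0.75 ± 0.09) and LHY (AT1G01060; -1.84 ± 0.38) of the circadian clock, where 7 of 24 rose and 1 fell. HFR1 (AT1G02340; 1.24 ± 0.18) and XTH15 (AT4G14130; 0.53 ± 0.08) belong to the PIF pathway, where 7 of 16 rose and 2 fell. In HY5-linked light signalling 3 of 12 fell and 0 rose, with ELIP2 (AT4G14690), a light stress protein of chloroplasts, at 60.8 CPM before and 18.6 CPM after. Auxin response had 3 rises and 2 falls of 23, such as DFL1 (AT5G54510; 0.52 ± 0.12), and auxin synthesis and transport 2 and 2 of 16. For brassinosteroid genes the counts were 4 higher and 2 lower of 12, with CYP90D1 (AT3G13730) at -1.30 ± 0.11, and for gibberellin genes 2 and 1 of 11, with GA20OX2 (AT5G51810), an enzyme of gibberellin synthesis, at 1.43 ± 0.17. Jasmonate genes rose in 5 and fell in 1 of 14, abscisic acid genes rose in 1 and fell in 4 of 12, endodermis and suberin genes rose in 3 and fell in 5 of 20, root hair genes fell in 4 of 19 with 0 higher, and root markers rose in 3 and fell in 10 of 24. Adjusted over the list alone, auxin response has 3 and 0, auxin synthesis 1 and 2 and the PIF pathway 8 and 2, and the other 9 counts do not move. Median, mean and camera's direction differ in sign for abscisic acid, auxin synthesis, brassinosteroid and endodermis, whose adjusted p were 0.587 to 0.804.

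In Col-0 shoots heat shock genes were mostly higher at 27 °C, and every measured gene of the flavonoid and anthocyanin list was lower. ASN1 (AT3G47340), an asparagine synthetase induced by low sugar, rose from 0.936 ± 0.503 to 40 ± 17 CPM (log2 fold change 5.39 ± 0.54, adjusted p = 3.93e-07), and SEN1 (AT4G35770), a gene of darkened and ageing leaves, from 1.57 ± 0.713 to 36.6 ± 13.4 CPM. Among further rises, DIN10 (AT5G20250) went from 109 ± 27.7 to 717 ± 210 CPM and the xylosidase BXL1 (AT5G49360) from 95 ± 18 to 590 ± 112 CPM. DFR (AT5G42800), which makes the first anthocyanin precursor, fell from 163 ± 83.1 to 6.71 ± 7.46 CPM, and ELIP1 (AT3G22840), a light stress protein of chloroplasts, fell from 142 ± 86.2 to 6.36 ± 1.52 CPM (adjusted p = 3.14e-07). Replicates at 21 °C spread widely for both genes, as their SD shows.

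Further rises in Col-0 shoots were those of BCAT-2 (AT1G10070; 3.01 ± 0.47), which breaks down branched amino acids, HSP90.1 (2.95 ± 0.16), HSP70 (AT3G12580), from 17.1 ± 3.32 to 129 ± 15.2 CPM, Hop3, from 4.18 ± 0.413 to 31.6 ± 1.44 CPM (adjusted p = 2.67e-12), MBF1C (2.76 ± 0.16) and CSLA14 (AT3G56000; 2.59 ± 0.18), a glucomannan synthase. Besides DFR, the falls include the anthocyanin enzymes LDOX (AT4G22880), from 119 ± 54.0 to 5.82 ± 4.71 CPM, UF3GT (AT5G54060; -4.51 ± 0.48) and AT5MAT (AT3G29590), from 30.7 ± 15.8 to 1.28 ± 1.03 CPM, the anthocyanin carrier GSTF12 (AT5G17220), from 52.1 ± 25.6 to 3.09 ± 3.06 CPM, and the chalcone synthase TT4 (AT5G13930), from 456 ± 189 to 37.5 ± 11.3 CPM. IRT1 fell here too, from 8.13 ± 1.71 to 0.258 ± 0.355 CPM, as did CYP82C4 (5.35 ± 2.31 to 0.430 ± 0.652 CPM) and NUDT24 (AT5G19470; 7.88 ± 1.06 to 0.308 ± 0.533 CPM). In all, 9173 of 20100 genes passed, 4514 higher and 4659 lower, of which 420 and 762 changed at least 2-fold.

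By group, 14 of 14 measured flavonoid genes fell in Col-0 shoots by either adjustment, such as FLS1 (AT5G08640), flavonol synthase, by 2.1 ± 0.16 and F3H (AT3G51240) from 97.2 to 9.62 CPM. Camera gave the list adjusted p = 1.13e-08, and adjusted p = 0.285 with an estimated correlation. Heat shock genes rose in 21 and fell in 1 of 30 (22 and 1 adjusted over the list alone). Camera called this list at adjusted p = 2.39e-09, and adjusted p = 0.0929 with an estimated correlation. Cold response genes fell in 11 of 14 with 0 higher by either adjustment, with KIN2 (AT5G15970) at -1.75 ± 0.12, KIN1 (AT5G15960) from 28.8 to 7.42 CPM and LTI78 (AT5G52310), a dehydration protein, from 30.5 ± 2.53 to 8.32 ± 0.268 CPM. The list's camera test gave adjusted p = 6.56e-05, and adjusted p = 0.285 with an estimated correlation. Ribosome biogenesis genes again fell in 13 of 13 by either adjustment, with NAP57 (AT3G57150), a pseudouridine synthase, from 129 to 73.4 CPM. For this list camera gave adjusted p = 7.77e-08, and adjusted p = 0.285 with an estimated correlation. Of 41 photosynthesis genes 28 rose and 7 fell by either adjustment. Most shifts were small, such as PSAF (AT1G31330; 3920 to 6050 CPM) of photosystem I, while RBCS1B (AT5G38430), a small Rubisco subunit with near-identical copies, fell from 2140 to 724 CPM. By camera the list had adjusted p = 0.000125, and adjusted p = 0.570 with an estimated correlation.

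The jasmonate list showed 8 falls and 1 rise of 16 in Col-0 shoots (9 and 2 adjusted over the list alone), with AOC2 (AT3G25770), allene oxide cyclase, at 149 ± 21.0 CPM before and 48.7 ± 10.4 after. Tested with camera, the list had adjusted p = 0.0176, and adjusted p = 0.539 with an estimated correlation. PIF pathway genes rose in 8 and fell in 2 of 16 by either adjustment, among them PAR1 (AT2G42870; 2.0 to 6.32 CPM) and PIL5 (AT2G20180; 0.60 ± 0.07), while PIF7 (AT5G61270) fell by 0.49 ± 0.06. Its camera test had adjusted p = 0.0302, and adjusted p = 0.510 with an estimated correlation. Iron deficiency genes fell in 8 and rose in 1 of 15. With camera, that list had adjusted p = 0.0302, and adjusted p = 0.570 with an estimated correlation. Salicylic acid genes fell in 6 of 18 with 0 higher, among them PR5 (AT1G75040; 8.83 to 2.12 CPM). Camera's result for it was adjusted p = 0.0305, and adjusted p = 0.570 with an estimated correlation. Unfolded protein genes rose in 7 of 15 with 0 lower. In camera this list had adjusted p = 0.00806, and adjusted p = 0.570 with an estimated correlation. These 3 lists keep their counts when adjusted over the list alone.

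The other 12 lists did not pass camera in Col-0 shoots. Nitrate genes moved both ways, 4 up and 5 down of 13, with the nitrate reductases NIA1 (AT1G77760; 209 ± 42.5 to 542 ± 57.3 CPM) and NIA2 (AT1G37130; 762 ± 37.2 to 1310 ± 70.8 CPM) higher and WR3 (AT5G50200) lower by 1.38 ± 0.13. Auxin synthesis and transport had 3 rises and 10 falls of 16, with YUC8 (AT4G28720), an auxin synthesis enzyme, at 0.88 ± 0.13 and CYP79B2 (AT4G39950) at -0.49 ± 0.08, and auxin response 3 and 3 of 31 (1 and 2 adjusted over the list alone), with IAA1 (AT4G14560) at -1.17 ± 0.15. Brassinosteroid genes had 1 and 1 of 12, with CPD (AT5G05690) at 0.83 ± 0.08, and gibberellin genes 4 and 4 of 13 (5 and 4 adjusted over the list alone), with GASA6 (AT1G74670) at 2.05 ± 0.26. The remaining counts of rises and falls were 1 and 6 of 13 for abscisic acid, 5 and 4 of 31 for cell cycle, 3 and 2 of 24 for the clock (2 and 1 adjusted over the list alone), 2 and 8 of 20 for endodermis and suberin, 1 and 5 of 12 for HY5-linked light signalling, 0 and 0 of 8 for root hair and 2 and 6 of 22 for root markers. Camera's adjusted p for these 12 lists were at least 0.0870.

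Root and shoot shared many calls. Among 18883 genes tested in both, 2350 were higher and 2499 lower at 27 °C in both tissues, where independent calls would give 978 and 991, and 345 were called in opposite directions. The correlation of log2 fold changes was 0.536 across genes, which are not independent replicates. The contrasts share no library. With an additional 2-fold minimum, 279 genes stayed in the same direction, of which the heat shock genes HSP90.1, Hop3 and MBF1C are examples.

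**Figure D3:**
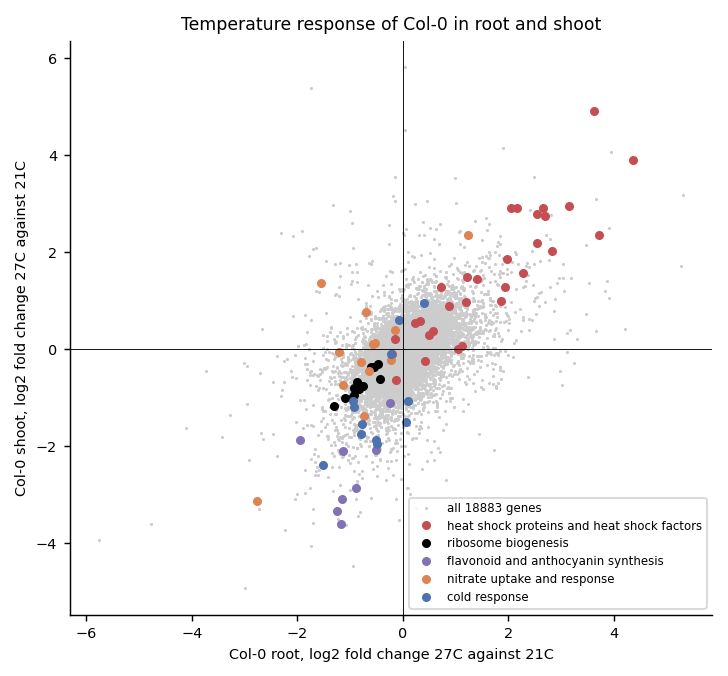
Log2 fold change at 27 °C against 21 °C in Col-0 roots (horizontal) and Col-0 shoots (vertical). Each point is 1 of 18883 genes, and colours mark members of the heat shock, ribosome biogenesis, flavonoid, nitrate and cold lists.

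The tissues also differed, with 3402 of 21598 genes called for a difference of responses, 1907 more positive in roots and 1495 in shoots. ASN1 stood at 26.2 ± 19.9 and 7.80 ± 6.32 CPM in Col-0 roots at 21 °C and 27 °C, against its rise in shoots (difference -7.12 ± 1.24, adjusted p = 0.000157). SEN1 (AT4G35770) stood at 6.04 ± 4.54 and 6.20 ± 3.73 CPM in roots (difference -4.49 ± 0.87, adjusted p = 0.000519). ELIP1 fell from 150 ± 18.8 to 78.5 ± 3.33 CPM in roots, less than in shoots (difference 3.54 ± 0.47, adjusted p = 4.93e-06). MES10 (AT3G50440), a methyl esterase, was near the limit of detection in roots, at 0.0477 ± 0.00462 and 0.987 ± 0.0997 CPM, and at 14.4 ± 2.05 and 19.3 ± 0.857 CPM in shoots (difference 3.75 ± 0.41, adjusted p = 1.60e-07). Nitrate genes had the lower response in roots, 7 of 13 lower and 1 higher (9 and 1 adjusted over the list alone), with NIA1 going from 93.8 ± 22.5 to 31.9 ± 5.56 CPM and NIA2 from 368 ± 6.07 to 226 ± 20.4 CPM in roots. Camera gave the list adjusted p = 3.16e-07, and adjusted p = 0.0973 with an estimated correlation. Flavonoid responses were less negative in roots in 6 of 14 (9 adjusted over the list alone), such as CHIL (AT5G05270; 1.97 ± 0.29) and 4CL3 (AT1G65060; 1.55 ± 0.29). Camera had adjusted p = 1.73e-07, and adjusted p = 0.177 with an estimated correlation. Not all 14 passed the root filter, so part of this may be the shoot fall alone.

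Salicylic acid genes had the higher response in roots in 7 of 19 (8 adjusted over the list alone), such as WRKY70 (1.97 ± 0.39). Camera had adjusted p = 1.82e-05, and adjusted p = 0.177 with an estimated correlation. Photosynthesis genes did so in 11 of 41 (15 adjusted over the list alone), such as HEMA1 (AT1G58290), the first enzyme of chlorophyll synthesis, at 0.89 ± 0.12, and LHCB4.1 at 1.01 ± 0.18. Here camera gave adjusted p = 0.000693, and adjusted p = 0.760 with an estimated correlation. Jasmonate genes did so in 5 of 16 by either adjustment, such as AOS (AT5G42650; 1.32 ± 0.19) and LOX4 (AT1G72520; 2.49 ± 0.48). Cold genes did in 4 of 15, such as LTI78 (1.36 ± 0.23) and KIN1 (1.46 ± 0.26). Camera gave adjusted p = 0.00785 for both lists, and adjusted p = 0.522 with an estimated correlation. The root filter likewise limits these lists and the salicylic acid list. Cell cycle genes had the lower response in roots in 6 of 31 (7 adjusted over the list alone), such as the cyclins CYCB1;3 (AT3G11520; -0.56 ± 0.16) and CYC1BAT (AT5G06150; -0.46 ± 0.14). Camera put them at adjusted p = 0.000693, and adjusted p = 0.522 with an estimated correlation.

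Heat shock and ribosome biogenesis genes were counted in hy5 and phyAB too. In hy5 roots 27 of 30 heat shock genes rose and 1 fell by either adjustment, and in phyAB roots 23 and 1 (24 and 1 adjusted over the list alone), with HSP90.1 going from 11.5 ± 2.96 to 122 ± 16.8 CPM in hy5 and from 9.60 ± 0.663 to 100 ± 1.82 CPM in phyAB. All 13 ribosome biogenesis genes fell in both mutants and both tissues by either adjustment, such as FIB2 in hy5 roots (320 to 109 CPM) and NAP57 in phyAB shoots (112 to 45.1 CPM). For heat shock genes in hy5 and phyAB roots camera had adjusted p = 4.64e-12 and 1.66e-13, and adjusted p = 0.209 and 0.149 with an estimated correlation. In hy5 and phyAB shoots it had 8.96e-10 and 3.35e-06, and adjusted p = 0.0802 and 0.180 with an estimated correlation. Ribosome biogenesis had at most 1.36e-09 in these 4 contrasts, and adjusted p = 0.180 to 0.438 with an estimated correlation. NSP3 was again among the largest falls of roots (-3.09 ± 0.18 in hy5 and -3.03 ± 0.18 in phyAB), and CYP82C4 fell in hy5 roots from 200 ± 75.9 to 8.5 ± 5.0 CPM. LHB1B2 (AT2G34420), a light-harvesting protein with near-identical copies, rose in hy5 roots from 1.44 ± 0.393 to 19.5 ± 14.1 CPM and in phyAB roots from 21.9 ± 6.09 to 185 ± 54.8 CPM, in libraries whose photosynthesis transcripts differ between replicates. In phyAB roots the flavonoid genes TT4 (31.0 ± 4.06 to 2.13 ± 0.268 CPM) and FLS1 (9.96 ± 1.85 to 0.933 ± 0.0288 CPM) and the clock gene LHY (71.5 ± 27.5 to 7.0 ± 1.2 CPM) were among the largest falls. Counts were 10097 genes in hy5 roots (5224 higher, 4873 lower) and 7802 in phyAB roots (3898 higher, 3904 lower).

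In shoots 23 of 30 heat shock genes rose and 1 fell in the libraries labelled hy5 by either adjustment, and 18 and 2 in phyAB (19 and 2 adjusted over the list alone). Flavonoid genes fell in 14 of 14 and 13 of 14 by either adjustment, such as DFR (137 ± 20.5 to 3.19 ± 1.53 CPM in hy5, 13.6 ± 8.12 to 0.656 ± 0.261 CPM in phyAB). SEN1 (AT4G35770) rose in hy5 shoots from 1.17 ± 0.322 to 12.8 ± 2.60 CPM and in phyAB shoots from 34.2 ± 7.09 to 249 ± 88.6 CPM. Genes of the PIF pathway rose in 11 and fell in 1 of 16 in phyAB shoots by either adjustment, with XTH15, a cell wall enzyme, going from 120 ± 13.2 to 734 ± 119 CPM. Its camera test had adjusted p = 0.000227, and adjusted p = 0.180 with an estimated correlation. In the same libraries seed transcripts summed to less at 27 °C for each replicate number, with 476 and 287 CPM, 1190 and 706 CPM, and 3250 and 1700 CPM at 21 °C and 27 °C in those numbered 1, 2 and 3. This difference was not tested. Counts were 9157 genes in hy5 shoots (4638 higher, 4519 lower) and 8721 in phyAB shoots (4279 higher, 4442 lower).

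**Figure D4:**
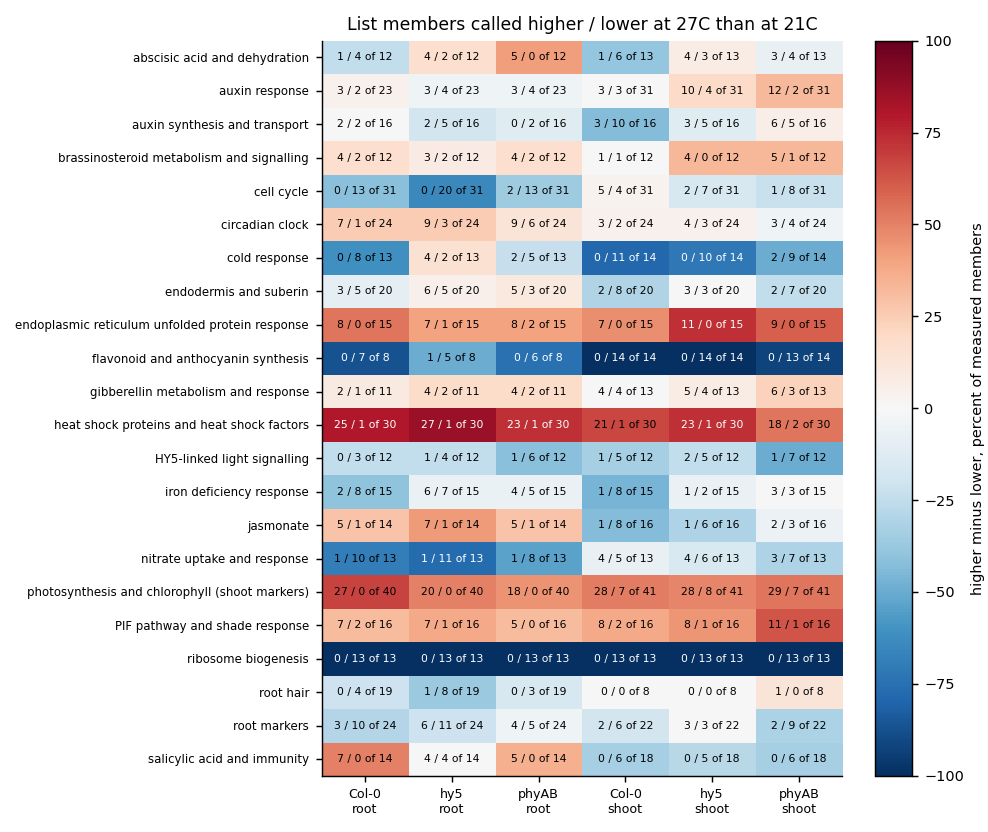
Members of the 22 lists that rose or fell at 27 °C in the 6 temperature contrasts, as higher / lower of measured. Colour gives higher minus lower as a percentage of measured members.

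Whether a mutation alters the temperature response was tested as a difference of responses. In hy5 roots 84 genes differed from Col-0, 48 with a more positive and 36 with a more negative response. CYP81F2 (AT5G57220), a cytochrome P450 of defence glucosinolates, stood at 3.75 ± 0.970 and 6.91 ± 1.56 CPM in Col-0 roots at 21 °C and 27 °C and at 16.4 ± 6.85 and 2.28 ± 0.771 CPM in hy5 (difference -3.72 ± 0.46, adjusted p = 0.00226). The immunity gene PBS3 (AT5G13320) went from 0.174 ± 0.0245 to 1.44 ± 0.204 CPM in Col-0 and from 2.70 ± 1.17 to 0.145 ± 0.0397 CPM in hy5. Cold genes showed the reverse, 3 of 13 more positive in hy5 and 0 more negative (5 and 0 adjusted over the list alone), with LTI78 going from 141 ± 10.3 to 98.9 ± 3.36 CPM in Col-0 and from 12.1 ± 1.11 to 17.9 ± 0.586 CPM in hy5 (difference 1.08 ± 0.17, adjusted p = 0.00607) and COR47 (AT1G20440) at a difference of 0.84 ± 0.12. With camera, that list had adjusted p = 7.14e-05, and adjusted p = 0.149 with an estimated correlation. ALMT1 (AT1G08430; 1.40 ± 0.25), a malate channel, MSRB6 (AT4G04840; 2.86 ± 0.62) and TT7 (AT5G07990; 2.78 ± 0.52), which was near absent in hy5 roots, had more positive responses, and the defence genes ALD1 (AT2G13810; -1.42 ± 0.25) and PER4 (AT1G14540; -1.25 ± 0.22) more negative ones. The count was 226 with DESeq2, 172 with a replicate block, 147 without a filter on low counts and 42 to 129 when 1 library was left out. The balance of directions turned with RLE size factors (38 more positive and 39 more negative), with DESeq2 (108 and 118) and in 7 of 12 cases with 1 library left out, most without hy5 21 °C replicate 3 (28 and 59) and Col-0 27 °C replicate 2 (21 and 40).

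In phyAB roots 20 genes differed, 6 more positive and 14 more negative. TK1a (AT3G07800), a thymidine kinase, stood at 12.9 ± 0.923 and 13.9 ± 0.543 CPM in Col-0 and at 23 ± 2.7 and 45.5 ± 2.46 CPM in phyAB (difference 0.85 ± 0.12, adjusted p = 0.00541). HYH (AT3G17609), the close relative of HY5, fell further in phyAB, from 15.1 ± 2.96 to 3.14 ± 0.750 CPM against 30.4 ± 2.83 to 15.5 ± 0.503 CPM in Col-0 (difference -1.28 ± 0.22, adjusted p = 0.0215). PAL1 (AT2G37040), the first enzyme of phenylpropanoid synthesis, had the more positive response (0.75 ± 0.13), and the proline dehydrogenase ERD5 (AT3G30775) the more negative one (-1.41 ± 0.26). The count was 9 without both libraries whose tissue labels conflict, 150 with DESeq2, 104 with a replicate block, 91 without a filter and 7 to 61 when 1 library was left out. In shoots labelled hy5 only the cyclophilin SQN (AT2G15790, chromosome 2) differed (difference 1.997 ± 0.16, adjusted p = 5.26e-06). It stood at 13.9 ± 0.239 and 10.9 ± 0.573 CPM in Col-0 and 32.1 ± 5.22 and 100 ± 15.1 CPM in hy5. At an unadjusted p under 0.05 there were 1870 genes, DESeq2 called 30, a replicate block gave 16, and leaving out 1 library gave 1 to 28.

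In phyAB shoots 706 genes had a different response from Col-0, 328 more positive and 378 more negative. Among genes with a more positive response, ST2A (AT5G07010) of the PIF pathway list went from 33.2 ± 1.67 to 120 ± 1.73 CPM in phyAB and from 1.80 ± 0.421 to 2.23 ± 0.255 CPM in Col-0 (difference 1.57 ± 0.20). HB-2 (AT4G16780), a shade-induced transcription factor, went from 11.1 ± 0.917 to 39.2 ± 6.96 CPM against 4.39 ± 0.765 to 6.79 ± 0.847 CPM (difference 1.18 ± 0.22). Among genes with a less positive response were ASN1 at 20 ± 7.9 and 80.8 ± 38.0 CPM in phyAB (difference -3.37 ± 0.69, adjusted p = 0.0130), BXL1 at 326 ± 75.5 and 608 ± 69.1 CPM (difference -1.74 ± 0.24, adjusted p = 0.000803) and DIN10 (difference -1.55 ± 0.31). AOC2 rose from 95.5 ± 11.5 to 128 ± 9.13 CPM in phyAB while it fell in Col-0 (difference 2.04 ± 0.23, adjusted p = 0.000196), and the fatty acid desaturase ADS1 (AT1G06080) went from 32.8 ± 8.67 to 111 ± 8.28 CPM (difference 2.22 ± 0.32, adjusted p = 0.00110). HSP90.1 rose less in phyAB, to 44.2 ± 4.69 CPM (difference -1.075 ± 0.22), as did the heat shock factor HSFA7A (AT3G51910; -1.25 ± 0.27).

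By group, 6 of 16 PIF pathway genes were more positive and 1 more negative in phyAB shoots (7 and 3 adjusted over the list alone). Camera's result for it was adjusted p = 0.00459, and adjusted p = 0.291 with an estimated correlation. Jasmonate genes were more positive in 4 of 16 (6 adjusted over the list alone). In camera this list had adjusted p = 0.000387, and adjusted p = 0.291 with an estimated correlation. Cold genes were more positive in 4 of 14 (5 adjusted over the list alone), such as ERD10 (0.91 ± 0.16), with camera at adjusted p = 0.000350, and adjusted p = 0.291 with an estimated correlation. Flavonoid genes were so in 3 of 14 (4 adjusted over the list alone), such as CHIL (1.64 ± 0.35), with adjusted p = 0.000227 in camera, and adjusted p = 0.360 with an estimated correlation. Heat shock genes were more negative in 4 of 30 (7 adjusted over the list alone), where camera had adjusted p = 0.000350, and adjusted p = 0.291 with an estimated correlation. For ribosome biogenesis genes it was 3 of 13 (8 adjusted over the list alone), such as NAP57 (-0.50 ± 0.11). Camera put them at adjusted p = 1.95e-05, and adjusted p = 0.354 with an estimated correlation. Seed transcripts of 287 to 3250 CPM lie beside these groups in every phyAB shoot. The count was 331 without the shoot libraries numbered 3, 1305 with a replicate block and 273 to 798 when 1 library was left out. Without Col-0 27 °C replicate 1 more were positive (416) than negative (382).

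In hy5 roots flavonoid, HY5-linked light signalling and photosynthesis genes were lower than in Col-0. At 21 °C TT7, a flavonoid hydroxylase, fell from 62.9 ± 14.4 CPM in Col-0 to 0.376 ± 0.219 CPM in hy5 (log2 fold change -7.29 ± 0.28, adjusted p = 5.98e-13), the photolyase-like CRY3 (AT5G24850) from 76.4 ± 4.57 to 0.749 ± 0.177 CPM, and UGT84A1, which glycosylates sinapate, from 19.7 ± 3.81 to 0.215 ± 0.0302 CPM. LHB1B2 fell from 112 ± 31.1 to 1.44 ± 0.393 CPM, and the embryo gene ATS3 (AT5G07190) from 9.60 ± 1.17 CPM to a level at which no hy5 library at 21 °C held a read. In the other direction the expansin EXPA16 (AT3G55500) rose from 0.797 ± 0.137 to 39.7 ± 17.9 CPM, scpl33 (AT3G17180) from 0.0979 ± 0.0540 to 5.13 ± 1.22 CPM, the glutamate receptor GLR2.2 (AT2G24720) from 0.221 ± 0.0747 to 6.18 ± 0.394 CPM and CYP76C4 (AT2G45550) from 0.303 ± 0.0847 to 6.67 ± 0.311 CPM. MRD1 (AT1G53480, chromosome 1) separated both mutants from Col-0 in each tissue, at 44.2 ± 3.19 CPM in hy5 roots and 43.8 ± 2.75 CPM in phyAB roots against 0.169 ± 0.292 CPM in Col-0 roots at 21 °C. At 27 °C, FLS1 stood at 2.01 ± 1.77 CPM in hy5 roots against 140 ± 8.43 CPM in Col-0, TT4 at 9.55 ± 7.04 against 489 ± 24 CPM, and MYB19 (AT5G52260) at 17 ± 1.2 against 1.23 ± 0.139 CPM. Counts were 7153 genes at 21 °C (3407 higher, 3746 lower in hy5) and 6797 at 27 °C (3265 higher, 3532 lower).

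By group, 8 of 8 flavonoid genes were lower in hy5 roots at both temperatures by either adjustment, such as TT5 (148 to 2.62 CPM at 21 °C). By camera the list had adjusted p = 3.02e-10 and 4.95e-11, and adjusted p = 0.0917 and 0.0801 with an estimated correlation. HY5-linked light signalling fell in 11 of 12 at 21 °C by either adjustment and in 10 at 27 °C (11 adjusted over the list alone), with ELIP2 from 60.8 to 2.03 CPM and RUP1 (AT5G52250), a repressor of UV-B signalling, from 19.5 to 1.1 CPM at 21 °C. Tested with camera, the list had adjusted p = 2.88e-09 and 1.10e-09, and adjusted p = 0.0458 and 0.0695 with an estimated correlation. Cold genes fell in 8 of 13 at both temperatures by either adjustment, with LTI78 from 141 ± 10.3 to 12.1 ± 1.11 CPM and COR47 from 1710 ± 207 to 508 ± 30.2 CPM at 21 °C. Its camera test had adjusted p = 2.69e-06 and 9.93e-05, and adjusted p = 0.0458 and 0.0801 with an estimated correlation. Photosynthesis genes fell in 33 and rose in 1 of 40 at 21 °C (33 and 2 adjusted over the list alone), with GUN5 (AT5G13630), a chlorophyll synthesis enzyme, from 86.8 to 4.33 CPM. With camera, that list had adjusted p = 1.01e-13, and adjusted p = 0.333 with an estimated correlation. Nitrate genes rose in 9 and fell in 3 of 13 (10 and 3 adjusted over the list alone), with the repressor LBD39 (AT4G37540) up by 1.06 ± 0.07 and NRT2:1 down by 3.36 ± 0.32. Camera's result for it was adjusted p = 0.00244, and adjusted p = 0.333 with an estimated correlation. Root hair genes fell in 7 and rose in 1 of 19 at 21 °C (8 and 1 adjusted over the list alone) and fell in 12 with 0 higher at 27 °C (13 adjusted over the list alone), with the wall protein PRP1 (AT1G54970) from 60.5 to 6.07 CPM at 21 °C. In camera this list had adjusted p = 0.0352 and 0.000877, and adjusted p = 0.793 and 0.713 with an estimated correlation.

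In phyAB roots ELIP1 stood at 1.82 ± 0.696 CPM against 150 ± 18.8 CPM in Col-0 at 21 °C (log2 fold change -6.34 ± 0.27, adjusted p = 4.93e-12), KIN1 at 1.92 ± 0.344 against 124 ± 15.3 CPM and TT7 at 0.641 ± 0.153 against 62.9 ± 14.4 CPM. At 27 °C TT4 stood at 2.13 ± 0.268 CPM in phyAB and 489 ± 24 CPM in Col-0, and FLS1 at 0.933 ± 0.0288 against 140 ± 8.43 CPM. Higher in phyAB roots were the patatin PLP4 (AT4G37050; 0.938 ± 0.245 to 13.8 ± 4.71 CPM), SWEET12 (2.01 ± 1.68 to 15.9 ± 7.36 CPM), the immunity gene ALD1 (2.38 ± 0.970 to 17 ± 1.7 CPM) and the anion channel gene SLAH1 (AT1G62280; 4.65 ± 0.615 to 33.6 ± 7.33 CPM) at 21 °C, and the transporter UMAMIT36 (AT1G70260; 3.48 ± 0.434 to 37.4 ± 3.36 CPM) and the lipase PLA2A (AT2G26560; 0.524 ± 0.171 to 5.40 ± 0.283 CPM) at 27 °C. Counts were 7161 genes at 21 °C (3508 higher, 3653 lower) and 6337 at 27 °C (2964 higher, 3373 lower).

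In phyAB roots 8 of 8 flavonoid genes were lower at both temperatures by either adjustment. Camera gave the list adjusted p = 1.39e-09 and 5.54e-12, and adjusted p = 0.101 and 0.0535 with an estimated correlation. Cold genes fell in 10 and rose in 1 of 13 at 21 °C and fell in 10 with 0 higher at 27 °C by either adjustment, with KIN2 from 209 ± 28.1 to 14.7 ± 3.76 CPM at 21 °C. Camera called this list at adjusted p = 1.26e-07 and 2.21e-07. HY5-linked genes fell in 10 and rose in 1 of 12 at 21 °C by either adjustment and fell in 10 at 27 °C with 0 higher (11 adjusted over the list alone), with RUP2 (AT5G23730) from 21.0 to 5.98 CPM at 21 °C. The list's camera test gave adjusted p = 4.30e-07 and 4.80e-10, and adjusted p = 0.0986 at 21 °C with an estimated correlation. Photosynthesis genes fell in 25 and rose in 1 of 40 at 21 °C by either adjustment, in libraries of which those numbered 2 held more of these transcripts than the other phyAB roots. For this list camera gave adjusted p = 1.59e-06, and adjusted p = 0.983 with an estimated correlation. Root hair genes fell in 13 and rose in 2 of 19 at 21 °C (14 and 2 adjusted over the list alone), with the root hair regulator RSL4 (AT1G27740) from 13.1 to 4.30 CPM. By camera the list had adjusted p = 0.00390, and adjusted p = 0.989 with an estimated correlation. Brassinosteroid genes rose in 6 of 12 with 0 lower by either adjustment, such as ROT3 (AT4G36380; 0.48 ± 0.06). Tested with camera, the list had adjusted p = 0.0312, and adjusted p = 0.477 with an estimated correlation. Of all camera calls, those that hold with an estimated correlation are cold and HY5-linked genes in hy5 roots at 21 °C (adjusted p = 0.0458 each) and in phyAB roots at 27 °C (0.0286 each), cold genes in phyAB roots at 21 °C (0.0385), and PIF pathway and auxin response genes in phyAB shoots at 21 °C (0.0404 each) and 27 °C (0.0265 each).

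The libraries labelled hy5 shoot differed from Col-0 shoots in fewer genes, 3604 at 21 °C (1807 higher, 1797 lower) and 2460 at 27 °C (1242 higher, 1218 lower). At 21 °C CSLA03 (AT1G23480), a glucomannan synthase, fell from 28.6 ± 3.85 to 1.04 ± 0.171 CPM (log2 fold change -4.76 ± 0.14, adjusted p = 1.30e-13), and KIN1 from 28.8 ± 3.32 to 1.68 ± 0.541 CPM. The iron regulators BHLH100 (AT2G41240), bHLH38 (AT3G56970) and bHLH39 (AT3G56980) were lower, at 0.536 ± 0.609, 0.620 ± 0.404 and 0.453 ± 0.279 CPM against 18.5 ± 11.4, 17 ± 9.1 and 9.5 ± 4.8 CPM in Col-0, where replicates spread widely. MRD1 (28.4 ± 1.47 against 0.711 ± 0.305 CPM), the lateral root gene AIR1 (AT4G12550; 6.84 ± 1.40 against 1.38 ± 0.368 CPM) and the P450 CYP71A12 (AT2G30750; 5.09 ± 2.11 against 1.06 ± 0.828 CPM) were higher. At 27 °C SQN (100 ± 15.1 against 10.9 ± 0.573 CPM) and the pectin methylesterase inhibitor gene ATPMEPCRD (AT2G43050; 8.39 ± 1.04 against 0.954 ± 0.0782 CPM) were higher, and the aminotransferase PYD4 (AT3G08860; 0.318 ± 0.145 against 4.62 ± 1.82 CPM) was lower. Without the shoot libraries numbered 3 the counts were 1762 at 21 °C and 1496 at 27 °C, and leaving out 1 library gave 2376 to 3167 and 1441 to 2137.

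Groups that marked hy5 roots were counted in the libraries labelled hy5 shoot too, without a test of the difference from roots. Summed seed transcripts, at 8.49 to 20.25 CPM in these libraries and at most 5.94 CPM in Col-0 shoots, lie beside all of them. Cold genes fell in 6 and rose in 2 of 14 at 21 °C (8 and 2 adjusted over the list alone), where camera had adjusted p = 0.00948, and adjusted p = 0.758 with an estimated correlation. Nitrate genes rose in 3 and fell in 1 of 13 (6 and 2 adjusted over the list alone), photosynthesis genes fell in 2 of 41 with 0 higher (1 adjusted over the list alone), and of 8 root hair genes 0 passed by either adjustment. Camera's adjusted p for these 3 lists were at least 0.127. Flavonoid genes fell in 2 of 14 at 21 °C by either adjustment, FLS1 (48.0 to 21.4 CPM) and MYB12 (AT2G47460; 1.89 to 0.338 CPM), and camera's adjusted p was 0.0637. HY5-linked genes fell in 2 of 12 by either adjustment at 27 °C, where camera's adjusted p was 0.0235, and adjusted p = 0.414 with an estimated correlation. Iron deficiency genes fell in 5 of 15 at 21 °C with 0 higher (12 adjusted over the list alone). Its camera test had adjusted p = 6.63e-05, and adjusted p = 0.758 with an estimated correlation. Ribosome biogenesis genes rose in 11 of 13 (13 adjusted over the list alone), such as TOZ (AT5G16750; 0.52 ± 0.08). With camera, that list had adjusted p = 2.73e-06, and adjusted p = 0.758 with an estimated correlation. At 27 °C unfolded protein genes rose in 7 of 15 with 0 lower (12 adjusted over the list alone), such as BIP2 (AT5G42020; 0.46 ± 0.10). Camera's result for it was adjusted p = 2.36e-06, and adjusted p = 0.414 with an estimated correlation. Auxin response genes rose in 8 of 31 with 0 lower (10 adjusted over the list alone), such as IAA2 (AT3G23030; 0.52 ± 0.10). In camera this list had adjusted p = 0.000108, and adjusted p = 0.414 with an estimated correlation.

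In phyAB shoots shade and auxin genes were raised at both temperatures. XTH15 stood at 120 ± 13.2 CPM against 2.67 ± 0.692 CPM in Col-0 at 21 °C and at 734 ± 119 against 7.33 ± 0.960 CPM at 27 °C, HFR1, a shade-induced regulator, at 36.2 against 1.58 CPM at 21 °C (log2 fold change 4.50 ± 0.14), and the auxin response gene IAA29 (AT4G32280) at 49.8 against 2.24 CPM. Of 16 PIF pathway genes, 13 rose and 1 fell at 21 °C and 12 and 1 at 27 °C by either adjustment. Camera gave the list adjusted p = 3.72e-09 and 1.21e-08. Of 31 auxin response genes, 25 rose at 21 °C and 27 at 27 °C with 0 lower (25 and 28 adjusted over the list alone), such as IAA19 (AT3G15540; 5.56 to 36.3 CPM at 21 °C) and WES1 (AT4G27260; 1.91 ± 0.10), which conjugates auxin. Camera had them at adjusted p = 3.52e-14 and 4.93e-16. Auxin synthesis and transport genes rose in 9 and fell in 2 of 16 at 21 °C (9 and 3 adjusted over the list alone), with YUC8 from 3.31 to 17.1 CPM. The list's camera test gave adjusted p = 0.00133, and adjusted p = 0.121 with an estimated correlation. Brassinosteroid genes rose in 10 and fell in 1 of 12 by either adjustment. For this list camera gave adjusted p = 0.00198, and adjusted p = 0.174 with an estimated correlation. Counts were 7681 genes at 21 °C (3614 higher, 4067 lower) and 8534 at 27 °C (3774 higher, 4760 lower).

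The largest rises in phyAB shoots were seed storage transcripts, with the cruciferins CRU3 (AT4G28520) at 394 ± 360 CPM and CRA1 (AT5G44120) at 596 ± 535 CPM at 21 °C against 0.129 ± 0.116 and 0.346 ± 0.179 CPM in Col-0, and the late embryo genes M17 (AT2G41260; 102 ± 88.8 CPM) and ATECP31 (AT3G22500; 10.6 ± 7.71 CPM), the latter listed at 0 in Col-0. CYP96A5 (AT2G21910), a cytochrome P450, was listed at 0 in Col-0 too and stood at 8.00 ± 0.0520 CPM at 21 °C and 18.3 ± 1.28 CPM at 27 °C, with a narrow spread that the seed transcripts lack. Photosynthesis genes were slightly lower, 37 of 41 with 1 higher at 21 °C (38 and 1 adjusted over the list alone), such as RBCS1A (AT1G67090; 34100 to 23900 CPM). By camera the list had adjusted p = 1.59e-09, and adjusted p = 0.421 with an estimated correlation. Flavonoid genes fell in 12 of 14 at 21 °C (13 adjusted over the list alone), such as UF3GT (30 to 1.90 CPM). Tested with camera, the list had adjusted p = 1.02e-05, and adjusted p = 0.421 with an estimated correlation. The iron regulator BHLH100 stood at 0.187 ± 0.0489 CPM against 18.5 ± 11.4 CPM. Heat shock genes rose in 11 and fell in 1 of 30 at 21 °C by either adjustment, among them HSP17.6A (AT5G12030; 0.0773 to 21.0 CPM), a small heat shock protein that seeds also hold. Its camera test had adjusted p = 0.0238, and adjusted p = 0.453 with an estimated correlation. Root markers rose in 9 and fell in 2 of 22 (10 and 3 adjusted over the list alone), such as the endodermal CASP1 (AT2G36100; 2.27 to 14.4 CPM). With camera, that list had adjusted p = 0.0238, and adjusted p = 0.453 with an estimated correlation. Endodermis and suberin genes rose in 10 and fell in 6 of 20 (11 and 6 adjusted over the list alone). Camera's result for it was adjusted p = 0.0491, and adjusted p = 0.518 with an estimated correlation. Summed seed transcripts of 476 to 3250 CPM at 21 °C and 287 to 1700 CPM at 27 °C lie beside all these groups of phyAB shoots, those of shade and auxin genes included.

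**Figure D5:**
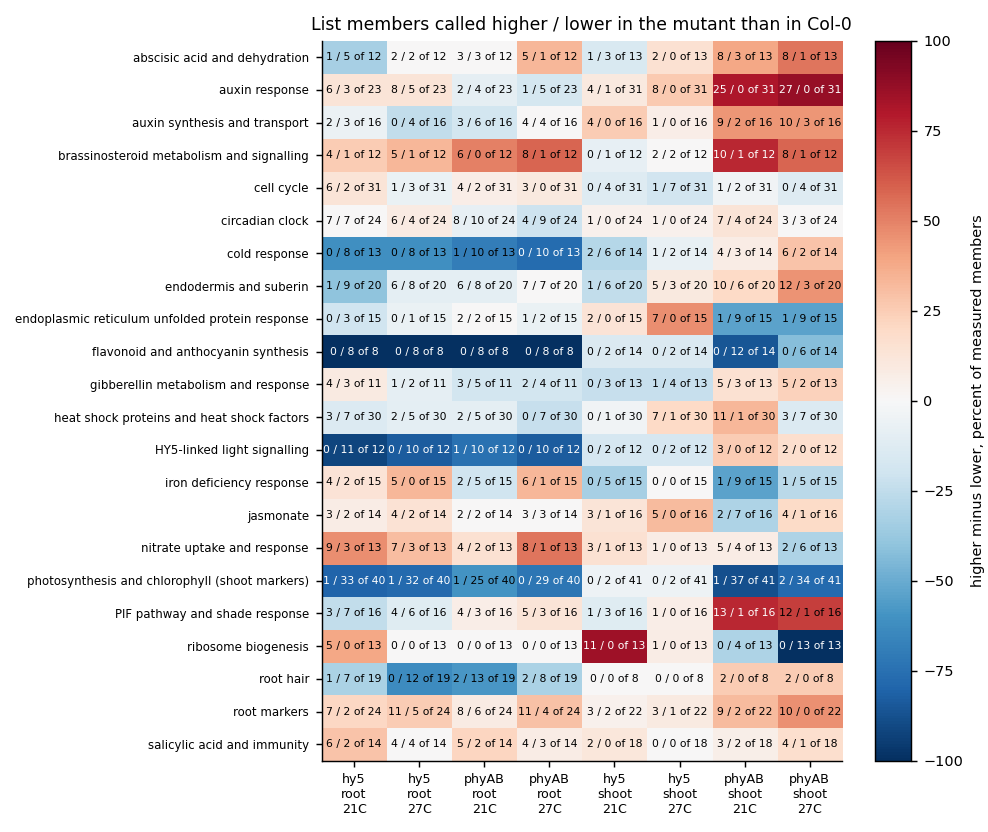
Members of the 22 lists that were higher or lower in a mutant than in Col-0 in the 8 genotype contrasts, as higher / lower of measured. Colour gives higher minus lower as a percentage of measured members.

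The overlap of both mutants was counted at 21 °C. In roots 1781 genes were higher and 2348 lower in hy5 and phyAB alike, where independent calls would give 587 and 672, and 169 were called in opposite directions, with TT7, ELIP1 and CHIL among those lower in both. The correlation across genes was 0.666, above the 0.470 (highest 0.509) of 20 simulations of unchanged mutants against the same Col-0 libraries, and the covariance was 0.404 against 0.0211. In shoots 336 were higher and 628 lower in both, where independent calls would give 325 and 364, and 753 were called in opposite directions. The shoot correlation was 0.279 and that of the simulations 0.484 (highest 0.544), which for the same reason cannot be compared. The covariance of 0.116 lies above the simulated 0.0295. No simulation gave a gene called in both, but 3 control libraries cannot be split, so part of either overlap may come from the shared controls. With an additional 2-fold minimum, 986 genes in roots and 179 in shoots stayed in the same direction, with 12 and 19 in opposite directions. In shoots at an adjusted p under 0.01 the counts were 400 and 223.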

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

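The tests of the HY5, seed and photosynthesis patterns, and the reading of splits that exchange equal numbers, were chosen only after the result was seen.

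The fall of HY5 transcript seen in hy5 roots did not pass in the libraries labelled hy5 shoot, where the mean was near that of Col-0 at 21 °C and lower without overlap of libraries at 27 °C (5.674 against 7.316 CPM). If these libraries held Col-0 shoots, loci that mark hy5 roots would not mark them, yet 11 of 11 loci at 1 CPM or more in every hy5 root and at 0.1 CPM or less in every other root also separate hy5 shoots from the other shoots. Low depth does not account for the missing fall at 21 °C either, since the 95% interval of the HY5 log2 fold change in shoots at 21 °C, -0.421 to 0.362, excludes the root value of -1.96. The marking loci lie on chromosomes 2, 3 and 4 and HY5 on chromosome 5. They mark the line and cannot tell which HY5 allele these shoots carry. What stays open is that allele and where along the gene the shoot reads map, and a shoot transcript of the mutant allele may be stable. None of these was analysed here.

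Seed storage transcripts stand high in phyAB shoots, with CRU3 at 104 to 1040, CRA1 at 137 to 1560 and OLEO1 at 3.59 to 56.8 CPM per library with the factors of the joint model, and 17 of 18 listed genes at a mean of 1 CPM or more. A level per library common to the listed genes holds 0.914 of the variance within genes, which is consistent with seeds or embryos mixed into these shoot samples in varying amounts. Against a technical difference shared by shoots numbered 3 stands a highest sum of 20.25 CPM in Col-0 and hy5 shoots numbered 3. The highest sum in phyAB roots, 2.6 CPM, argues against an effect of the genotype in the whole seedling. An effect of the genotype limited to shoots stays open and untested.

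Photosynthesis transcripts are higher at 27 °C in Col-0 roots and lower in hy5 roots than in Col-0 roots at 21 °C. Carried-over shoot RNA would have to supply a median of 0.277% of root RNA for the first pattern and 0.214% for the other. Abundant shoot genes allow 0.0883% and 0.0487%, the fifth lowest bound of 20 (0.00403% to 2.05% and 0.0129% to 1.11%). All 27 called members of the first and 31 of 33 of the other need more. This argues only against RNA of shoots as sampled here. Parts of shoots, root tissue with more or fewer green plastids, or another mix of cells stay open and untested.

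In hy5 roots the count of 84 genes with a different temperature response comes with log2 differences of 2.86 for MSRB6, 2.78 for TT7, 1.46 for KIN2, 1.40 for ALMT1, 1.08 for LTI78 and 0.84 for COR47. Negative ones were -7.205 for PBS3, -3.72 for CYP81F2, -1.42 for ALD1, -1.25 for PER4, -1.18 for EDA39 and -1.08 for PFA-DSP2. For the 20 genes of phyAB roots they were 0.85 for TK1a, 0.75 for PAL1, 0.61 for SAHH2, -1.73 for ROXY2, -1.41 for ERD5, -1.30 for RABA6b, -1.28 for HYH and -1.07 for BZO2H3. The 1 gene of hy5 shoots, SQN, had 1.997.

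Among the 706 genes of phyAB shoots the differences were 2.35 for TT7, 2.32 for COR413IM1, 2.22 for ADS1 (AT1G06080), 2.185 for LSU3, 2.04 for AOC2, 1.64 for CHIL, 1.57 for ST2A, 1.18 for HB-2 and 1.02 for KIN2. Smaller ones were 0.996 for AOS, 0.92 for IAA19, 0.91 for ERD10 and 0.64 for ABI2. Less positive responses were -3.37 for ASN1, -1.74 for BXL1, -1.60 for HMT3, -1.55 for DIN10, -1.50 for CYP710A1, -1.25 for HSFA7A, -1.075 for HSP90.1, -0.50 for NAP57 and -0.44 for NOP56.

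The 3402 genes that differ between tissues in Col-0, root minus shoot, include ATH1 at 3.96, MES10 at 3.75, PBS3 at 3.74, bHLH071 at 3.69, ELIP1 at 3.54, TIR at 3.19 and LOX4 at 2.49. CHIL and WRKY70 stood at 1.97 each, 4CL3 at 1.55, KIN1 at 1.46, LTI78 at 1.36, AOS at 1.32, LHCB4.1 at 1.01 and HEMA1 at 0.89. On the negative side were ASN1 at -7.12, SEN1 (AT4G35770) at -4.49, STP14 at -4.07, MYB16 at -3.12, THA1 at -3.07, NIA1 at -2.93, NIA2 at -1.475, CYCB1;3 at -0.56 and CYC1BAT at -0.46. Reads at more than 1 place made up 27.8% in the Col-0, 34.6% in the hy5 and 28.8% in the phyAB shoot library numbered 3 at 27 °C, and the genes they come from were not analysed here.

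For the 14 comparisons of 3 with 3 libraries, 10 splits are too few to test chance, as only the real one, 1 of 10, gave as many genes. Their real counts were 2460 to 10097, and the highest other split gave 0, except for 10 in the Col-0 and 35 in the phyAB shoot temperature response and 1 for phyAB against Col-0 roots at 27 °C. For differences of responses 100 splits were drawn. Chance cannot be excluded from them, as 11 gave at least 84 genes in hy5 roots (highest other 9637), 11 at least 20 in phyAB roots (9457), 15 at least 1 in hy5 shoots (5592), 11 at least 706 in phyAB shoots (10898) and 24 at least 3402 between tissues (18271). Splits with several times the real count point to a structure of the samples, the lasting difference between genotypes or tissues, which enters when unequal numbers of libraries are exchanged at 21 °C and 27 °C. Among the 34 drawn splits that exchange equal numbers, the highest gave 0 genes for 4 of the differences and 1 for hy5 shoots, where the real count is 1.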

How the results depend on the processing

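Leaving out the phyAB roots numbered 2, the 6 shoots numbered 3 and the Col-0 shoots numbered 3 were tests chosen only after the result was seen. With RLE size factors all 19 counts of called genes stayed within 1.5 times, and no scaling moved the median of all genes by over 0.1. Leaving out 1 library moved 29 of 144 counts by more than 1.5 times. Among named genes the call was lost in 20 of 1366 cases with DESeq2, 7 of 1367 with RLE factors, 6 of 1367 without a filter on low counts, 1 of 1367 with a replicate block, 42 of 1357 with only the groups compared and 719 of 9054 with 1 library left out. A single direction was reversed, that of RD22 (AT5G25610) in the temperature response of phyAB roots, from 1.08 to -0.042 without those numbered 2. Of 418 list tests, called or not, 147 lost their call with an estimated correlation. The other 271 are the tests that were not called to begin with and the few calls that held, which the Results name. Most camera calls were thus lost. Counts of list members moved by over 1.5 times, or to or from 0, in 780 of 6336 cases with 1 library left out, 55 of 836 with DESeq2, 83 of 836 with a replicate block, 84 of 836 with only the groups compared, 26 of 836 without a filter, 14 of 836 with RLE factors and 70 of 396 without the shoots numbered 3. They moved in 25 of 176 without phyAB roots numbered 2, 28 of 176 without those with conflicting tissue labels and 11 of 44 without Col-0 shoots numbered 3. The share of genes with the more positive response in roots was 56.1% between tissues and 67.5% with only the groups compared, and DESeq2 gave 46.7% of more positive genes in the hy5 shoot difference.

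Without a filter the differences had 147 genes in hy5 roots, 91 in phyAB roots and 4 in hy5 shoots, with DESeq2 226, 150 and 30, and with a replicate block 172, 104 and 16, beside 1305 in phyAB shoots. With only the groups compared the hy5 shoot difference had 2. All 3 correlations were above 0.1 only in the phyAB root temperature response and both 27 °C shoot comparisons with Col-0. There the block gave 8243, 3070 and 9060 genes and moved no count by over 1.5 times. Yet all 6 libraries of the phyAB shoot temperature response correlated best with their own number (0.209, 0.038 and 0.209). The same held between Col-0 roots and shoots at both temperatures and between phyAB roots and shoots at 21 °C. Pairing stays possible in all these, and the models without a block leave it out. The phyAB root difference had 9 genes without both libraries with conflicting tissue labels and 12 without both numbered 2. Without the 6 shoots numbered 3 the phyAB shoot difference had 331 genes, and hy5 shoots differed from Col-0 in 1762 at 21 °C and 1496 at 27 °C. Overlaps with a 2-fold minimum held 279 genes for root and shoot, 986 for both mutants in roots and 179 in shoots, and 400 in shoots at an adjusted p under 0.01.

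Single libraries moved the hy5 root difference to 42 (without hy5 27 °C replicate 2), 51 (Col-0 21 °C replicate 1), 54 (Col-0 27 °C replicate 3) and 129 (Col-0 27 °C replicate 1). The phyAB root difference went to 7 without Col-0 21 °C replicate 2 or Col-0 27 °C replicate 3, to 12 and 61 without Col-0 27 °C replicates 2 and 1, to 13 and 31 without phyAB 21 °C replicates 2 and 3, and to 11 and 9 without phyAB 27 °C replicates 2 and 3. In the hy5 shoot difference the count was 28 without Col-0 27 °C replicate 1, 3 without hy5 21 °C replicate 3 and 2 without Col-0 21 °C replicate 2 or 3 or replicate 1 of either hy5 group. The phyAB shoot difference went to 273, 423 and 798 without Col-0 27 °C replicates 2, 3 and 1, to 397 without Col-0 21 °C replicate 2, to 455 and 466 without phyAB 21 °C replicates 2 and 3, and to 461 without phyAB 27 °C replicate 3. For hy5 against Col-0 shoots at 21 °C the count was 2376 without hy5 replicate 2 and at most 3167, without hy5 replicate 1. At 27 °C it was 1441, 1558 and 2137 without hy5 replicates 1, 2 and 3, and 1569 and 1561 without Col-0 replicates 2 and 3.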

Other observations

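All tests of the hypothesis on the hy5 line were chosen only after the result was seen. Further groups stand out by their counts at 27 °C. Of 13 nitrate genes 7 rose and 3 fell in hy5 roots (8 and 3 adjusted over the list alone), and 8 rose and 1 fell in phyAB roots by either adjustment. The repressor LBD37 (AT5G67420) stood at 180 CPM in hy5 and 181 CPM in phyAB against 119 CPM in Col-0. Camera's adjusted p were 0.0192 and 0.00565, and adjusted p = 0.521 and 0.440 with an estimated correlation. Iron deficiency genes rose in 5 of 15 in hy5 with 0 lower and in 6 with 1 lower in phyAB by either adjustment, among them BTS (AT3G18290; 0.53 ± 0.11 and 0.78 ± 0.11). Here camera had adjusted p = 0.0437 and 0.0460, and adjusted p = 0.748 and 0.666 with an estimated correlation. In phyAB shoots at 27 °C, where seed transcripts sum to 287, 706 and 1700 CPM against at most 20.25 CPM in Col-0 and hy5 shoots, all 13 ribosome biogenesis genes were lower than in Col-0 by either adjustment, such as FIB2, at 19.5 ± 5.05 against 37.5 ± 4.84 CPM, with camera at adjusted p = 3.64e-05, and adjusted p = 0.335 with an estimated correlation. Suberin and endodermis genes rose in 12 and fell in 3 of 20 there by either adjustment, such as FAR1 (AT5G22500), which makes fatty alcohols of suberin, at 360 ± 43.0 against 18.6 ± 1.01 CPM. Adjusted p in camera was 0.00261, and adjusted p = 0.335 with an estimated correlation. Root markers rose in 10 of 22 with 0 lower in these libraries by either adjustment, such as CASP1, at 7.68 ± 2.32 against 2.91 ± 0.362 CPM. For root markers camera had adjusted p = 0.00825, and adjusted p = 0.335 with an estimated correlation.

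Of 11 loci read in hy5 libraries and near 0 in all others, 8 lie on chromosome 2, which holds 5174 of 32548 genes (15.9%). A 1-sided Fisher's exact test gave p = 4.25e-05, and 0.000212 after multiplying by 5 chromosomes. AT2G03965 is the most abundant, at 175 to 300 CPM in hy5 roots and 345 to 614 CPM in hy5 shoots. HY5 lies on chromosome 5. A candidate explanation is thus a chromosome 2 segment of the hy5 line that differs from others, as from a cross or another background. Under it, part of the difference between hy5 and Col-0 may belong to that segment and not to HY5. SQN and ALD1, on chromosome 2 too, may be such cases. Sequence variants, which could show a segment, were not used here. In phyAB 1 locus behaves in the same way, and MRD1 separates both mutants from Col-0, so that line may differ in background too.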
